A study of Arabidopsis thaliana with 24 samples.

How the data were processed

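Transcript levels were measured on 24 Affymetrix whole-transcript arrays, each hybridised with total RNA of Arabidopsis thaliana labelled with biotin. The arrays fall into 8 groups of 3, made of 4 genotypes (Col-0 wild type, WT; hd2c-3; brm-1; brm-1 hd2c-3) in control or heat conditions. Per the labels' protocols, the plants grew on soil with 16 h light and 8 h dark at 70% humidity, and 3-week-old plants were moved to 38 °C for 1 h. The deposited values are log2 intensities, 1 value for each of 38408 probe sets and each array. The submitters' processing notes name RMA and Partek, without versions, settings or the order of steps, and no batch correction is recorded. The array medians lay between 3.42 and 3.65 on the log2 scale. The number of arrays limits the precision of every comparison.

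The deposited platform table names genes for 17504 of the 38408 probe sets. Of these, 16746 carry 1 gene and 758 carry several, and the latter were left out together with the 20904 probe sets without a name. Where a gene had more than 1 probe set, the one with the highest mean over all arrays stood for it, which left 16552 genes. Names were matched to a reference gene table of assembly TAIR10.1, used only for names and for which genes are neighbours. It held 16418 of the genes, and 134 were kept under the name in the platform table. No probe set is named for BRM, HD2C, any heat shock factor, HSP101 or HSP90.1, so these genes were not analysed here and the mutant labels were not checked against the targeted transcripts.

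All 24 arrays entered a single linear model with 1 mean per group in limma 3.58.1 under R 4.3.3, with 16 residual degrees of freedom and empirical Bayes moderation (prior degrees of freedom 6.25). From it 19 contrasts were tested, all two-sided. They were the heat response of each genotype, each mutant against WT and the double mutant against each single mutant in each condition, the difference of each mutant's heat response from that of WT, and the departure of the double mutant from the sum of the single-mutant effects in each condition. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 16552 genes. Fold changes are given on the log2 scale unless stated otherwise, and each ± in the report and in the closing section is the moderated standard error (SE) unless SD is written, with 3 arrays in each group. The SE and the p pool the spread of a gene over all 8 groups. They come out too small where the groups compared vary more than the rest, and too large where they vary less. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01. The tests were adjusted over lists and contrasts in 5 families, namely heat responses, genotypes in control, genotypes in heat, double against single mutants, and differences. The same tests were repeated with an estimated correlation. Matplotlib 3.10.9 drew the plots.

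The comparisons, tests, alternatives, the rule for naming genes and 26 gene lists with 370 genes were fixed before the data were examined. Only 73 of the 370 genes have a named probe set. In the camera tests, 24 lists with at least 3 measured genes were used, 12 of them from the lists fixed before and 12 families added once the names on the array were known and before any fold change was computed. The families reported below are J-domain proteins, cytosolic ribosomal proteins, expansins with xyloglucan endotransglucosylases, UDP-glycosyltransferases and serine carboxypeptidase-like genes. An added family of defensin-like genes was corrected after fold changes had been seen, because peptide deformylases share its symbol prefix, and it was called in none of the contrasts.

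The rule named, in each comparison, up to 4 called members of each list with the largest fold changes, and the 5 largest rises and falls among called genes with a symbol. In both cases the values of the 2 groups may not overlap. Every called gene was named where a comparison had 10 or fewer. The rule also named BRM, HD2C, the heat shock factors, HSP101 and HSP90.1, which have no named probe set. The text presents a part of the genes that the rule names. Genes named outside the rule are marked as chosen after their values were seen.

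The method was tested on simulated data before use, with each gene's mean and pooled spread over all arrays and known changes. Genes were drawn independently, with equal spread in all groups. In the data the median SD of a gene ran from 0.109 in WT control to 0.186 in double mutant heat. The shares below therefore hold for the simulated setting and need not carry over to the real contrasts. For the heat response in WT, 17.9% of genes changed by 0.5 were recovered, 76.1% of those changed by 1 and 100% of those changed by 2, with 9.15% false calls. For hd2c against WT in control the shares were 22.4%, 89.6% and 100%, with 4.08% false calls. For the difference in heat response of hd2c from WT they were 1.49%, 47.8% and 95.5%. For the departure from additivity in heat they were 7.46%, 46.3% and 98.5%.

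Replicate numbers 1, 2 and 3 occur in every group, and the labels do not say that a number marks a shared batch. Deviations of same-numbered arrays from their group means were correlated across genes in the 14 comparisons of 2 groups. The rule that all 3 pairs exceed an r of 0.1 was met in 3 comparisons: brm against WT in heat (0.159, 0.109, 0.161), the double mutant against hd2c in control (0.282, 0.174, 0.407) and the double mutant against brm in control (0.258, 0.211, 0.415). In these 3, each of the 6 arrays correlated best with the array of its own number. Between genotypes in control, 4 to 6 of the 6 arrays did so in each comparison, and in heat 1 to 6. Between heat and control 0 to 2 did. Shared structure by number within a condition is thus not limited to these 3 comparisons, and the main model has no replicate term. Any pairing rests on the values alone, and genes are not independent replicates in these correlations.

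The alternatives were cyclic loess normalization, a common array median, leaving out the dimmest 30% of genes, an intensity trend with robust moderation, no moderation, fits of only the arrays of the groups compared, array weights, a replicate block, and leaving out each array in turn. A pair of further alternatives was chosen after seeing the data, namely testing all probe sets together and a replicate block within each condition. The closing section gives their effects.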

Results

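Expression was profiled in Arabidopsis plants lacking the histone deacetylase HD2C, the chromatin remodelling ATPase BRAHMA (BRM), or both, to compare how these chromatin factors shape the transcriptome in control conditions and after a short heat stress. Each of the 4 genotypes was sampled in control conditions and after 1 h at 38 °C, with 3 biological replicates per group and 24 arrays in all. The series' design text says that replicates were chosen for similar expression of marker genes, which it does not name, so the spread between replicates may be understated. The first principal component held 43.8% of the variance and parted all heat arrays from all control arrays. The second held 12% and parted the arrays of brm and of the double mutant, with scores from −19.4 to −8.74, from those of WT and hd2c, with scores from 13.0 to 18.4.

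The first question was how WT plants respond to heat. Genes of chaperones were among the largest rises. AT2G29500, a cytosolic class I small heat shock protein that binds unfolding proteins, rose by 8.03 ± 0.12 (261-fold, n = 3 per group, adjusted p = 1.38e-22), and the endomembrane type ATHSP22.0 rose by 6.82 ± 0.27. Among co-chaperones, ROF2 (AT5G48570, a peptidyl-prolyl isomerase) rose by 7.12 ± 0.18 and Hop3, which links HSP70 to HSP90, by 5.83 ± 0.22. HSA32, needed for the memory of acquired thermotolerance, rose by 5.15 ± 0.25, and the chloroplast chaperonin subunit Cpn60beta2 by 3.53 ± 0.19. Genes of anthocyanin synthesis were lower: UF3GT fell by 2.45 ± 0.39, DFR (dihydroflavonol reductase) fell by 2.38 ± 0.39 and the anthocyanin malonyltransferase AT5MAT fell by 2.08 ± 0.30.

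In all, 2198 genes were called in the WT heat response, 960 higher and 1238 lower, of which 394 changed at least 2-fold. Of 11 measured small heat shock proteins 10 were higher and 1 was not called, also when adjusted over the list alone (camera adjusted p = 2.05e-32, and 0.00109 with an estimated correlation). Of 8 co-chaperones and other heat-induced genes 6 were higher, and 7 adjusted over the list alone (adjusted p = 5.02e-17, and 0.00136 with an estimated correlation). In the unfolded protein response of the endoplasmic reticulum 3 of 5 measured genes were higher, and 5 adjusted over the list alone, among them ATERDJ3B (1.31 ± 0.16) and CRT1b (0.91 ± 0.10) (adjusted p = 1.78e-05, and 0.0274 with an estimated correlation). All 3 measured flavonoid genes were lower over all genes and adjusted over the list alone (adjusted p = 2.66e-05, but 0.0564 with an estimated correlation). Among 5 cold response genes KIN1 was higher (1.18 ± 0.23) and 3 were lower, with the same counts adjusted over the list alone, and COR15B fell by 1.39 ± 0.15. That list's adjusted p was 0.0471, and 0.257 with an estimated correlation. Of 10 J-domain proteins, an added list of HSP70 partners, 4 were higher and 6 were not called (adjusted p = 1.18e-04, and 0.00926 with an estimated correlation).

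Part of the heat response was common to all 4 genotypes. In hd2c, AT2G29500 rose by 8.99 ± 0.12, the HSP70 exchange factor Fes1A by 4.29 ± 0.36 (2.40 ± 0.36 in WT), and BZIP60, a transcription factor of endoplasmic reticulum stress, by 1.59 ± 0.23. In brm, AT2G29500 rose by 8.15 ± 0.12 and the J-domain protein AT2G20560 by 4.73 ± 0.34, while the sugar transporter SWEET4 fell by 1.74 ± 0.14. In the double mutant, ATHSP22.0 rose by 8.18 ± 0.27, whereas DFR fell by 3.53 ± 0.39 and the spindle checkpoint gene BUBR1 fell by 2.05 ± 0.21 (n = 3 per group). The dehydrin COR47 rose there by 2.46 ± 0.23, a rise that WT did not share. All 11 small heat shock proteins were higher in brm and in the double mutant, and 10 in hd2c, with camera adjusted p of 1.40e-35, 3.42e-30 and 5.41e-27 and no more than 0.00136 with an estimated correlation. Co-chaperones were higher in 7, 6 and 7 of 8 cases in hd2c, brm and the double mutant, with the same counts adjusted over the list alone (adjusted p up to 6.19e-15, and up to 0.00194 with an estimated correlation). Unfolded protein response genes were higher in 5, 4 and 5 of 5 cases, and in all 5 adjusted over the list alone (adjusted p up to 1.29e-06, and up to 0.0132 with an estimated correlation).

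hd2c had 3316 called genes in its heat response (1469 higher, 1847 lower), brm 2613 (1205 higher, 1408 lower) and the double mutant 3553 (1552 higher, 2001 lower). The balance depended on the scaling: in brm 1323 were higher and 1117 lower with equal array medians, and in the double mutant 1866 were higher and 1748 lower under cyclic loess. In all 4 genotypes, 426 genes were called higher and 592 lower, out of 5608 called in any. Fold changes in WT correlated across genes with those in hd2c (r = 0.83), brm (r = 0.78) and the double mutant (r = 0.75), although genes are not independent replicates. These pairs of responses share no array. WT and the double mutant shared 614 rises and 876 falls, where independent lists would share 90.0 and 150, and 16 genes were called in opposite directions. Flavonoid genes fell in 3 of 3 cases in each mutant, over all genes and adjusted over the list alone, with adjusted p of 2.19e-04 in hd2c, 0.00332 in brm and 7.03e-04 in the double mutant. With an estimated correlation these were 0.0924, 0.206 and 0.128. J-domain proteins were higher in 6, 4 and 6 of 10 cases in hd2c, brm and the double mutant, with p up to 0.00576 at an estimated correlation. Of 98 cytosolic ribosomal proteins, an added list, 17 were lower and none higher in brm (adjusted p = 2.89e-06, but 0.271 with an estimated correlation). Of 7 serine carboxypeptidase-like genes, also added, 3 were lower and none higher in the double mutant, SCPL34 among them (adjusted p = 0.0225, but 0.0598 with an estimated correlation).

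**Figure D1:**
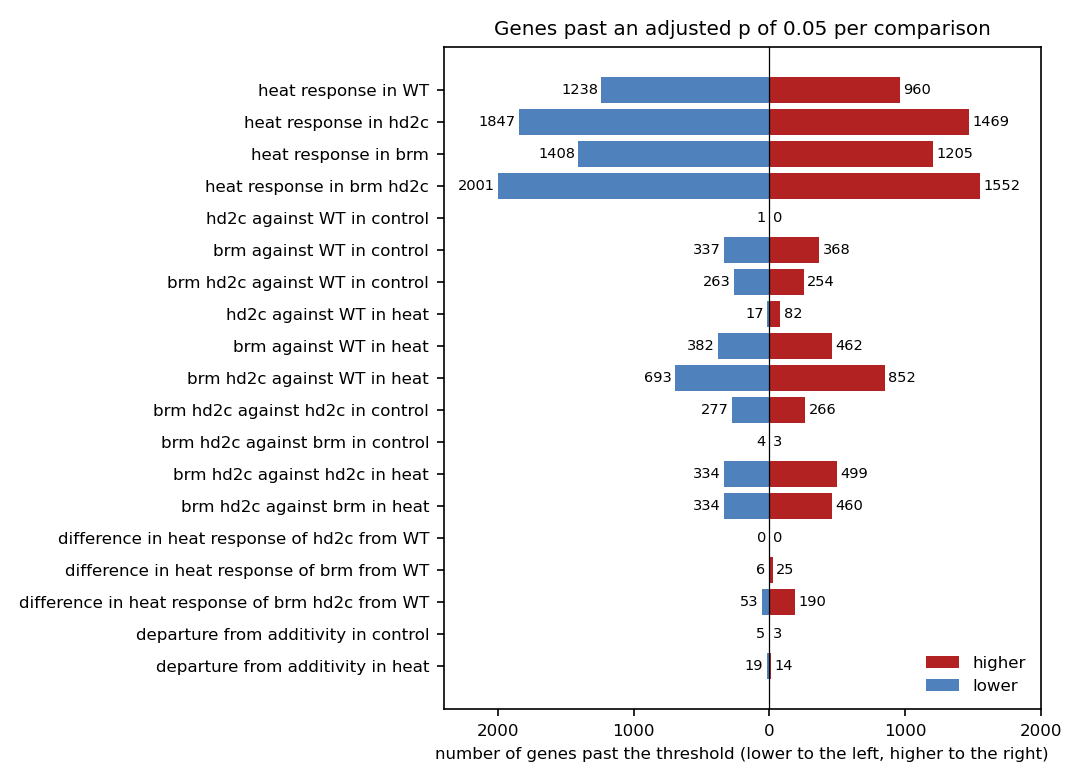
Number of genes past an adjusted p of 0.05 in each of 19 comparisons (n = 3 arrays per group), with lower genes to the left and higher genes to the right on a linear axis. Heat responses had 2198 to 3553 genes, and hd2c against WT in control had 1.

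The comparison of hd2c with WT in control conditions asks what the loss of this deacetylase changes without stress. The locus AT3G01345 fell by 6.18 ± 0.34 in hd2c (n = 3 per group, adjusted p = 1.09e-10), from a mean of 9.32 ± 0.15 (SD) in WT to 3.13 ± 0.09 (SD). AT3G01345 was also low in the other mutant groups, at 4.20 ± 0.99 (SD) in brm and 4.58 ± 0.59 (SD) in the double mutant in control. In heat its level was 8.66 ± 0.32 (SD) in WT and between 3.49 ± 0.14 and 4.74 ± 0.50 (SD) in the mutants. It was the only gene called by limma in hd2c against WT in control, and it kept its call when any 1 array was left out. At an unadjusted p under 0.05 there were 418 genes, against 828 expected by chance in a calibrated test. With 418 below that level, the test may be conservative in this comparison, which was not tested. The count of called genes was 2 without WT control replicate 3 and 3 with array weights. Cytosolic ribosomal proteins had a camera adjusted p of 8.35e-06, with 0 of 98 called by limma, 2 higher at an unadjusted p under 0.05 and a median of 0.11, but the adjusted p was 0.395 with an estimated correlation.

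Many genes differed between brm and WT in control conditions. UGT84A3, a glucosyltransferase of hydroxycinnamates, fell by 2.70 ± 0.15 in brm (n = 3 per group, adjusted p = 2.54e-10), the YABBY transcription factor YAB5 of leaf development fell by 1.77 ± 0.12, and the floral promoter AGL24 fell by 1.55 ± 0.16. The antimicrobial thionin THI2.1 fell by 1.83 ± 0.25 and DFR fell by 2.28 ± 0.39. QQS, a gene without known relatives that affects leaf starch, rose by 2.41 ± 0.23, the cell wall invertase relative cwINV6 by 1.86 ± 0.30 and SWEET4 by 1.64 ± 0.14. The bromodomain gene AT1G76380, whose product is a subunit of SWI/SNF complexes like BRM itself, rose by 1.06 ± 0.13.

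A total of 705 genes were called in brm against WT in control, 368 higher and 337 lower. With all array medians set equal, 41.2% of called genes were higher in place of 52.2%. All 3 flavonoid genes were lower over all genes and adjusted over the list alone (camera adjusted p = 8.35e-06, but 0.139 with an estimated correlation). Of 5 cold response genes COR15A was lower (by −0.98 ± 0.12) and 4 were not called, and 3 were lower adjusted over the list alone (adjusted p = 0.00232, but 0.166 with an estimated correlation). Of 9 SWI/SNF subunits only AT1G76380 was called, also adjusted over the list alone (adjusted p = 0.0292, but 0.270 with an estimated correlation). Of 31 expansins and xyloglucan endotransglucosylases, an added list of wall-loosening proteins, 4 were higher and 27 not called, with EXPA15 up by 1.36 ± 0.22 and EXPB1 by 1.22 ± 0.18 (adjusted p = 0.0424, but 0.304 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.21 with 0 of 98 called by limma and 18 higher at an unadjusted p under 0.05 (adjusted p = 1.04e-08, but 0.270 with an estimated correlation). The number of called genes fell to 460 without WT control replicate 1, 469 without WT control replicate 3 and 458 without brm control replicate 2. It was 1322 with array weights.

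The double mutant in control asks what the joint loss changes. UGT84A3 fell by 2.38 ± 0.15 against WT, YAB5 fell by 1.79 ± 0.12 and AGL24 fell by 1.54 ± 0.16, values close to those of brm, and WRKY42, a regulator of phosphate and leaf senescence genes, fell by 1.73 ± 0.17. SWEET4 rose by 1.51 ± 0.14, the wax ester synthase WSD1 by 1.59 ± 0.27 and AT1G76380 by 1.24 ± 0.13. Cold response genes were lower: COR47 fell by 1.45 ± 0.23 and COR15A, a protector of chloroplast membranes, fell by 1.37 ± 0.12 (n = 3 per group). In that list 3 of 5 genes were lower, and 4 adjusted over the list alone (camera adjusted p = 1.04e-08, and 0.00923 with an estimated correlation). In all 517 genes were called, 254 higher and 263 lower. The 3 flavonoid genes were all lower, also adjusted over the list alone (adjusted p = 8.35e-06, but 0.139 with an estimated correlation). The count was 308 without WT control replicate 3 and 902 with array weights.

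The double mutant was next compared with hd2c in control. UGT84A3 fell by 2.45 ± 0.15 in the double mutant against hd2c, WRKY42 fell by 1.90 ± 0.17 and YAB5 fell by 1.85 ± 0.12, whereas the jacalin lectin JAL34 rose by 1.62 ± 0.18 and QQS by 1.58 ± 0.23 (n = 3 per group). AT1G76380 rose by 1.28 ± 0.13 and its relative AT1G20670 by 0.56 ± 0.11. A total of 543 genes were called, 266 higher and 277 lower. Of 9 SWI/SNF subunits 3 were higher, also adjusted over the list alone (camera adjusted p = 0.0122, but 0.204 with an estimated correlation). Of 5 cold response genes 3 were lower, and 5 adjusted over the list alone (adjusted p = 7.69e-09, and 0.00905 with an estimated correlation). Of 51 UDP-glycosyltransferases, an added list, 7 were lower and none higher (adjusted p = 0.00540, but 0.171 with an estimated correlation). The count was 351 without hd2c control replicate 1, 343 without hd2c control replicate 2, 339 without double mutant control replicate 1 and 844 with array weights.

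Few genes differed between the double mutant and brm in control. AT2G20870, a cell wall protein precursor, rose by 2.38 ± 0.32 in the double mutant against brm (n = 3 per group, adjusted p = 0.00391), and it was the only one of 7 called genes to keep its call when any 1 array was left out. The others were AT5G22430 (1.70 ± 0.25) and AT5G56840 (1.14 ± 0.19), which were higher, and AT2G04495, the pectin methylesterase ATPMEPCRB, AT5G05190 and AT5G52740, which fell by 1.57 ± 0.26, 1.30 ± 0.20, 0.87 ± 0.15 and 0.82 ± 0.15. The share of higher genes was 42.9%, 60% with equal array medians and 50% with cyclic loess. Cold response genes had 0 of 5 called by limma, with 3 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 1.79e-04, but 0.110 with an estimated correlation). The count of 7 was 41 without brm control replicate 1, 2 without brm control replicate 2, 3 without brm control replicate 3, 3 without double mutant control replicate 2 and 1 without double mutant control replicate 3. It was 14 with array weights and 0 in limma without moderation, against 938 genes at an unadjusted p under 0.05 in the moderated fit.

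The effect of brm could be compared in the presence and absence of HD2C with separate arrays. In control, fold changes of brm against WT and of the double mutant against hd2c correlated across genes (r = 0.56), although genes are not independent replicates. They shared 152 rises and 154 falls, where independent lists would share 5.91 and 5.64, and 3 genes were called in opposite directions. UGT84A3, AGL24, YAB5, COR15A and AT1G76380 changed the same way in both. In heat r was 0.47, with 183 shared rises and 148 shared falls against 13.9 and 7.71 for independent lists, and 2 genes in opposite directions. The effect of hd2c with and without BRM correlated weakly in control (r = −0.09) and more in heat (r = 0.34), where 27 rises and 6 falls were shared against 2.28 and 0.343 for independent lists. There 3 genes were called in opposite directions, and the list of hd2c against WT in heat fell from 99 genes to 3 without WT heat replicate 1. All these pairs share no array.

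**Figure D2:**
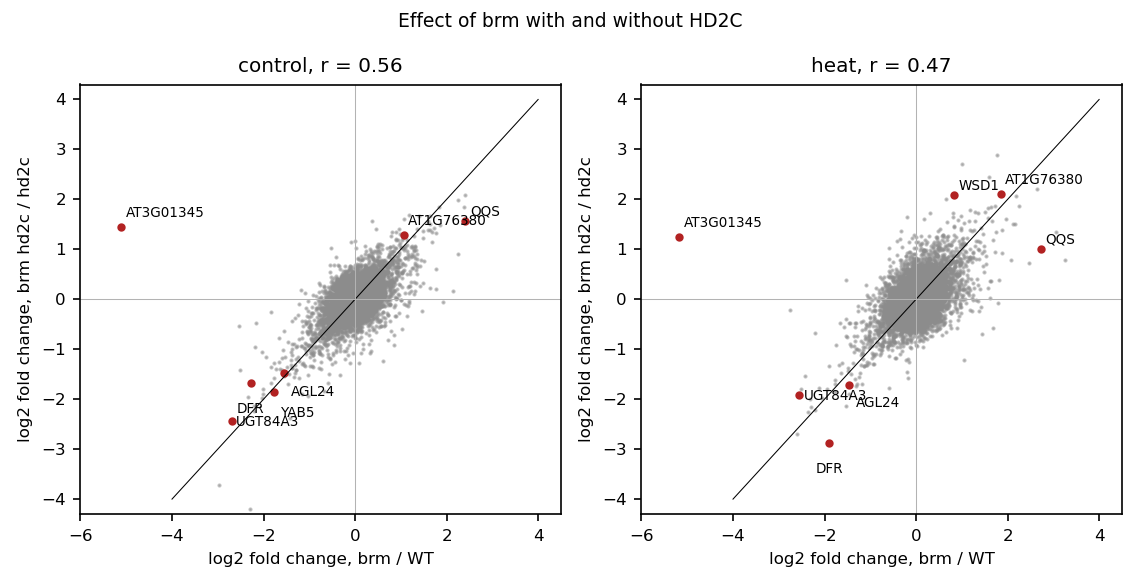
Log2 fold change of brm against WT (horizontal axis) and of brm hd2c against hd2c (vertical axis) for 16552 genes as points, in control (left, r = 0.56) and heat (right, r = 0.47), with a line of equal values. The genes marked in red were chosen after their values were seen, and AT3G01345 lies apart in both plots.

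After heat, hd2c plants had more of several heat-induced transcripts than WT. AT1G52560, an organellar small heat shock protein, was higher by 2.25 ± 0.35 (n = 3 per group, adjusted p = 0.00469), AT5G37670 of the same family by 1.83 ± 0.33 and Fes1A by 1.69 ± 0.36. These genes varied more within the 2 groups than the pooled spread behind the ±. In heated hd2c and heated WT the SD was 0.95 and 0.63 for AT1G52560, 0.71 and 0.75 for AT5G37670, and 0.79 and 1.00 for Fes1A. The co-chaperone SGT1A was higher by 1.01 ± 0.18 and BZIP60 by 1.12 ± 0.23. Of 99 called genes, 82 were higher and 17 lower. Small heat shock proteins were higher in 5 of 11 cases, and in 9 adjusted over the list alone (camera adjusted p = 2.42e-09, but 0.0948 with an estimated correlation). Co-chaperones were higher in 3 of 8, and in 7 adjusted over the list alone (adjusted p = 1.79e-08, but 0.0897 with an estimated correlation), and unfolded protein response genes in 1 of 5, and in 4 adjusted over the list alone (adjusted p = 4.79e-04, but 0.106 with an estimated correlation). All 13 genes that the naming rule gives here lost their call without WT heat replicate 1 (3 genes called in all) and without hd2c heat replicate 2 (4 genes). The count was 52 without WT heat replicate 3, 357 without hd2c heat replicate 1, 39 without hd2c heat replicate 3, 151 with an intensity trend, 64 without moderation and 3 in a fit of only the 6 arrays. That last fit uses the spread of these 6 arrays alone and has fewer degrees of freedom.

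Many genes also differed between brm and WT in heat. UGT84A3 fell by 2.55 ± 0.15 against WT (adjusted p = 3.90e-10, n = 3 per group), PMEAMT, a phosphoethanolamine methyltransferase of membrane lipid synthesis, fell by 1.77 ± 0.14 and AGL24 fell by 1.47 ± 0.16. QQS was higher by 2.73 ± 0.23, cwINV6 by 1.96 ± 0.30 and AT1G76380 by 1.85 ± 0.13. Among chaperones, AT5G37670 was higher by 1.69 ± 0.33, SGT1A by 1.61 ± 0.18, Hsp70-2 by 1.48 ± 0.25 and Hop3 by 1.03 ± 0.22. Fold changes of brm against WT in control and in heat correlated across genes (r = 0.52), with 164 rises and 163 falls shared and 1 gene opposite, against 10.3 and 7.78 for independent lists.

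In brm against WT in heat 844 genes were called, 462 higher and 382 lower. Small heat shock proteins were higher in 4 of 11 cases, and in 6 adjusted over the list alone (camera adjusted p = 3.68e-05, but 0.193 with an estimated correlation). Co-chaperones were higher in 4 of 8 cases, and adjusted over the list alone 5 were higher and 1 was lower (adjusted p = 3.68e-05, but 0.110 with an estimated correlation). Of 9 SWI/SNF subunits 3 were higher, the bromodomain genes AT1G76380, AT5G55040 (0.64 ± 0.14) and AT1G20670 (0.62 ± 0.11), and adjusted over the list alone 3 were higher and 1 lower (adjusted p = 0.00665, but 0.110 with an estimated correlation). Of 51 UDP-glycosyltransferases 9 were lower and 2 higher (adjusted p = 0.0272, but 0.193 with an estimated correlation). DFR was the single flavonoid gene called of 3 (fell by 1.90 ± 0.39), and 2 were lower adjusted over the list alone (adjusted p = 0.00665, but 0.220 with an estimated correlation). The count was 1290 with array weights and 531 in a fit of only the arrays compared.

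Of the mutants, the double mutant had the most called genes against WT in heat. WSD1 was higher by 2.73 ± 0.27, ABR1, an ERF transcription factor of abscisic acid responses, by 2.35 ± 0.35, AT1G52560 by 2.22 ± 0.35, Fes1A by 2.05 ± 0.36 and COR47 by 1.15 ± 0.23 (n = 3 per group). DFR fell by 3.09 ± 0.39, the plant defensin PDF1.2 fell by 2.11 ± 0.45 and AGL24 fell by 1.85 ± 0.16. Of 1545 called genes, 852 were higher and 693 lower. Of the small heat shock proteins 7 of 11 were higher, and 10 adjusted over the list alone (camera adjusted p = 5.67e-09, but 0.0948 with an estimated correlation). Co-chaperones were higher in 6 of 8 cases, also adjusted over the list alone (adjusted p = 3.95e-06, but 0.0948 with an estimated correlation). Flavonoid genes were lower in 2 of 3, and in 3 adjusted over the list alone (adjusted p = 8.85e-04, but 0.173 with an estimated correlation). Wall-loosening genes were higher in 4 of 31 cases (adjusted p = 0.0185, but 0.184 with an estimated correlation). In a fit of only the arrays compared 694 genes were called.

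The double mutant was also compared with each single mutant in heat. Against hd2c, AT1G76380 was higher by 2.11 ± 0.13, WSD1 by 2.09 ± 0.27 and SWEET4 by 1.75 ± 0.14, while DFR fell by 2.88 ± 0.39, UGT84A3 fell by 1.91 ± 0.15 and PMEAMT fell by 1.85 ± 0.14 (n = 3 per group). Against brm, ABR1 was higher by 2.76 ± 0.35, AT1G52560 by 2.02 ± 0.35, COR47 by 1.74 ± 0.23 and the cold-induced gene KIN1 by 1.41 ± 0.23. QQS fell by 1.92 ± 0.23, and the cell division genes AUR1, an Aurora kinase, and TOPII, a topoisomerase, fell by 1.16 ± 0.21 and 1.04 ± 0.15. Against hd2c 833 genes were called, 499 higher and 334 lower, and against brm 794, 460 higher and 334 lower. Against brm 3 of 5 cold response genes were higher, also adjusted over the list alone (camera adjusted p = 0.00235, but 0.171 with an estimated correlation), and 2 of 11 small heat shock proteins, or 3 adjusted over the list alone (adjusted p = 0.0346, but 0.772 with an estimated correlation). Against hd2c 2 of 9 SWI/SNF subunits were higher, and adjusted over the list alone 3 were higher and 1 lower (adjusted p = 0.0197, but 0.240 with an estimated correlation). The count against brm was 384 without brm heat replicate 3 and 400 without double mutant heat replicate 3. In fits of only the arrays compared the counts were 215 against hd2c and 165 against brm, and with array weights 504 against hd2c.

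**Figure D3:**
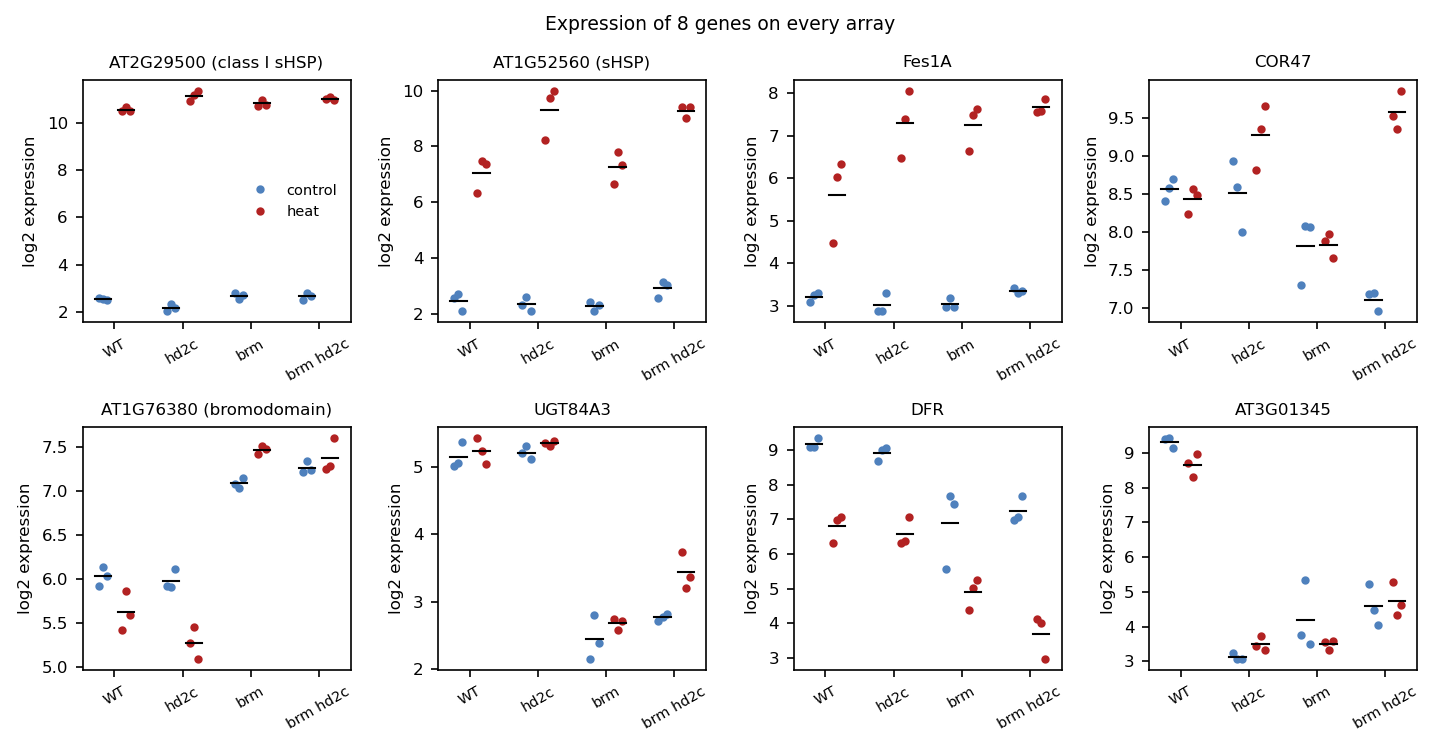
Log2 expression of 8 genes on each of the 24 arrays (points, 3 per group) with group means (lines), by genotype, in control (blue) and heat (red), for genes chosen after their values were seen. COR47 means went from 7.11 in control to 9.58 in heat in the double mutant and from 8.56 to 8.43 in WT.

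Whether a mutant's heat response differs from that of WT was tested as an interaction. For the double mutant, the response of ABR1 was higher by 3.25 ± 0.50, that of COR47 by 2.60 ± 0.32, that of the small heat shock protein AT4G21870 by 1.66 ± 0.33 and that of COR15B by 1.05 ± 0.21, while TOPII had a lower response, by −1.05 ± 0.21 (n = 3 per group). These genes kept their calls when any 1 array was left out. Cold response genes differed upwards in 3 of 5 cases, and in 5 adjusted over the list alone (camera adjusted p = 7.34e-10, and 0.00801 with an estimated correlation). A positive difference need not be a stronger induction. COR15B fell with heat in WT, and its difference is a smaller fall. COR47 in the double mutant was below WT in control and above it in heat, so both conditions contribute. In control 3 of 5 genes of this list were lower in the double mutant than in WT. In all 243 genes were called for the double mutant, 190 with a positive and 53 with a negative difference. Small heat shock proteins had a median difference of 1.11, with 1 of 11 called and 6 adjusted over the list alone (adjusted p = 3.89e-07, but 0.198 with an estimated correlation). Co-chaperones had 1 of 8 called, ROF2 (AT5G48570, 1.03 ± 0.26), and 5 adjusted over the list alone (adjusted p = 2.90e-05, but 0.198 with an estimated correlation). ROF2 lost its call in 10 of the 12 fits without 1 array. The count of 243 was 147 without WT control replicate 3, 154 without double mutant control replicate 3, 160 without WT heat replicate 3 and 138 without double mutant heat replicate 3.

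For brm, UGT87A2, a glycosyltransferase that affects flowering time, had a lower response than in WT (difference −1.15 ± 0.20, n = 3 per group), and it was the only one of 8 genes named there to keep its call when any 1 array was left out. In all 31 genes were called, 25 positive and 6 negative (80.6% positive, and 93.7% with equal array medians). J-domain proteins had 1 of 10 called, AT3G14200 with a difference of 1.71 (adjusted p = 2.02e-04, and 0.0445 with an estimated correlation). Its call was lost without WT control replicate 1, brm control replicate 3, brm heat replicate 2 or brm heat replicate 3 (adjusted p up to 0.0638). Small heat shock proteins had 0 of 11 called by limma, 4 higher adjusted over the list alone and 5 at an unadjusted p under 0.05 (adjusted p = 2.90e-05, but 0.261 with an estimated correlation). Cytosolic ribosomal proteins had a median of −0.21 with 0 of 98 called by limma and 13 lower at an unadjusted p under 0.05 (adjusted p = 7.34e-10, but 0.213 with an estimated correlation). The count of 31 was 18 without WT control replicate 1, 17 without WT control replicate 3, 16 without brm control replicate 2, 16 without brm control replicate 3, 20 without WT heat replicate 1, 11 without brm heat replicate 2 and 14 without brm heat replicate 3. Other settings gave 180 (array weights), 71 (intensity trend), 63 (equal array medians), 59 (cyclic loess), 53 (dimmest genes left out) and 20 (all probe sets together).

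For hd2c, limma called 0 genes in the difference, with 1105 at an unadjusted p under 0.05 against 828 expected by chance. Small heat shock proteins had a median difference of 0.87, with 0 of 11 called, 8 higher adjusted over the list alone and 8 at an unadjusted p under 0.05 (camera adjusted p = 5.72e-10, but 0.124 with an estimated correlation). Co-chaperones had 0 of 8 called, 3 higher adjusted over the list alone and 5 at an unadjusted p under 0.05 (adjusted p = 2.90e-05, but 0.198 with an estimated correlation). Leaving out hd2c heat replicate 1 gave 71 called genes, and leaving out hd2c control replicate 1 gave 1. Other settings gave up to 16.

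The size of the whole heat response was summarised per heat array as an amplitude score relative to the mean response of all genotypes, a measure chosen after the fold changes had been seen. WT arrays scored 0.835 ± 0.0708 (SD, n = 3), hd2c 1.07 ± 0.135, brm 0.920 ± 0.0307 and the double mutant 1.06 ± 0.0406. Every array of each mutant lay above every WT array, and the exact two-sided permutation p of each mutant against WT was 0.1, the smallest that 3 against 3 arrays allow. Mutants make up most of the reference. A response that they share and WT lacks therefore raises their scores over WT without a larger amplitude. In a first version of the score, each genotype had another reference; it gave means of 0.760, 1.06, 0.843 and 1.01 and the same p of 0.1.

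**Figure D4:**
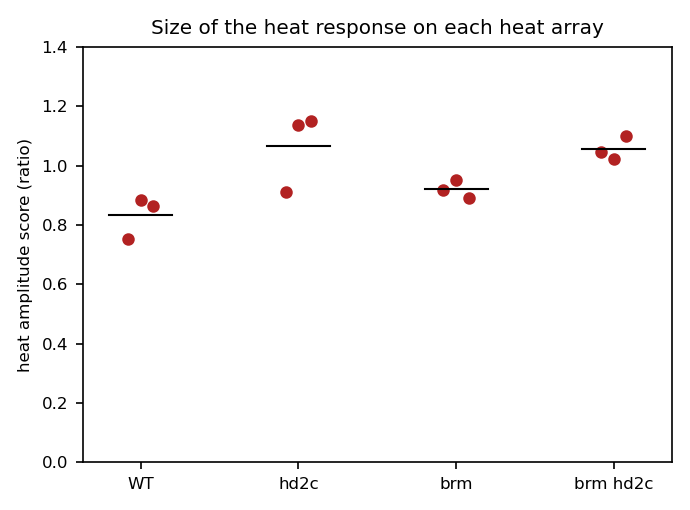
Heat amplitude score (a ratio without unit) of each heat array as a point, with the mean of each genotype as a line (n = 3). WT arrays lie between 0.754 and 0.885 and double mutant arrays between 1.02 and 1.10.

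Departure from additivity asks whether the double mutant differs from the sum of the single-mutant effects. In control, AT3G01345 departed by 6.56 ± 0.48 (n = 3 per group), since its level was low in each mutant and no lower in the double mutant. Additivity would need a level of −1.99 there, below the lowest gene value on any array (0.548), so no level in the double mutant could have met it. The low levels in both single mutants thus fixed this departure. The gene was 1 of 8 called (3 positive, 5 negative), and none of the other 7 kept its call when any 1 array was left out. ATPMEPCRB (−1.76), AT2G04495 (−1.98) and AT5G56840 (1.58) were among the others. The share of positive genes was 37.5%, and 100% with equal array medians. The count of 8 was 1 without WT control replicate 1, 2 without WT control replicate 3, 1 without hd2c control replicate 1, 5 without hd2c control replicate 2, 37 without brm control replicate 1, 2 without brm control replicate 2, 2 without brm control replicate 3, 4 without double mutant control replicate 1, 3 without double mutant control replicate 2 and 3 without double mutant control replicate 3. Other settings gave between 1 and 17.

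In heat, 3 chaperone genes that were called higher in each single mutant departed downwards from the sum. The single-mutant effects and the departure use the same WT heat arrays. A low WT mean raises the effects and lowers the departure, so picking genes higher in each single mutant favours a negative departure. The small heat shock protein AT5G37670 departed by −2.26 ± 0.47, the co-chaperone SGT1A by −1.24 ± 0.25 and Hop2 by −1.05, and of the other genes QQS departed by −1.71 ± 0.32 (n = 3 per group). In all 33 genes were called, 14 positive and 19 negative (42.4% positive, and 22.9% with equal array medians). AT3G01345 was 1 of them (6.41), and its additive level of −1.67 again lay below the lowest gene value on any array. Co-chaperones had 2 of 8 called, and 4 lower adjusted over the list alone (camera adjusted p = 4.05e-04, but 0.238 with an estimated correlation). J-domain proteins had 1 of 10 called, AT1G56300 (adjusted p = 3.58e-05, and 0.0313 with an estimated correlation). None of the 9 genes that the naming rule gives here kept its call in every fit without 1 array. The count of 33 was 9, 20 and 6 without WT heat replicates 1, 2 and 3, 71, 7 and 6 without hd2c heat replicates 1, 2 and 3, 21, 12 and 8 without brm heat replicates 1, 2 and 3, and 15 and 6 without double mutant heat replicates 1 and 3. Other settings gave between 3 and 57.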

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

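The tests by 4-group regrouping, the heat exposure test and the loess correlation of the brm effect were chosen only after their results were seen. Single arrays were not tested within their groups of 3. Array weights estimated over all 24 arrays ranged from 0.353 (double mutant heat replicate 1) and 0.449 (brm heat replicate 1) to 1.72 (WT control replicate 2).

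Differences in heat response between a mutant and WT were found by the interaction test for 31 genes in brm and 243 in the double mutant. In brm the named genes were AT3G14200 (1.71), ARL (1.50), ZCF37 (1.35), DER1 (1.13), YAB5 (0.86) and TRM22 (0.81), with positive differences, and YAO (−1.26) and UGT87A2 (−1.15). Of these 8 genes only UGT87A2 kept its call in every fit without 1 array. In the double mutant they were ABR1 (3.25), COR47 (2.60), LTI30 (1.81), NTMC2T6.2 (1.67), AT4G21870 (1.66), ATPMEPCRB (1.48), EXLA2 (1.36), AGL94 (1.33), COR15B (1.05), AT5G48570 (1.03) and KIN2 (0.65). SFP2 (−1.56), 3xHMG-box1 (−1.17), NET3C (−1.12), TOPII (−1.05) and BUB3.1 (−1.04) had negative differences. Of these 16 genes, ABR1, COR47, AT4G21870, ATPMEPCRB, EXLA2, AGL94, COR15B, SFP2 and TOPII kept their calls in every such fit, and the other 7 did not. Of 100 regroupings of the arrays, with additive effects taken out first, only the real grouping gave 31 genes for brm (highest other 1) and only the real one gave 243 for the double mutant (highest other 4), so chance can be excluded for both counts among these groupings. They did not keep replicate numbers together, although same-numbered arrays correlated in brm against WT in heat. Among all 32 groupings that exchange labels only between arrays of 1 condition and replicate number, again only the real one gave as many (highest other 1 for brm and 4 for the double mutant). Without that step 13 and 5 of 100 groupings gave as many (highest other 1462 and 594), because regrouping then mixes heat with genotype. For hd2c, limma called 0 genes, with 1105 at an unadjusted p under 0.05. All 100 groupings then give as many by construction (highest other 1), so regrouping says nothing about this result.

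Departures of the double mutant from additivity were found for 8 genes in control and 33 in heat. In control they were AT3G01345 (6.56), AT5G56840 (1.58), AT1G27420 (1.22), AT5G52740 (−1.16), AT1G53035 (−1.36), AT1G78410 (−1.63), ATPMEPCRB (−1.76) and AT2G04495 (−1.98). In heat the named genes were GLR3.5 (1.23), UGT87A2 (0.99), SAT32 (0.93), AT1G56300 (−0.84), Hop2 (−1.05), SGT1A (−1.24), QQS (−1.71), bZIP42 (−1.87) and AT5G37670 (−2.26). Of these genes other than AT3G01345, none kept its call in every fit without 1 array. AT3G01345 was also called in heat (6.41), and its calls in control and heat say nothing about how the 2 losses combine. Additivity would need a level of −1.99 in control and −1.67 in heat, below the lowest gene value on any array (0.548). Only the real one of 100 groupings gave 8 genes in control (highest other 2), and 2 of 100, the real one included, gave 33 or more in heat. These groupings did not keep replicate numbers together, although same-numbered control arrays correlated in both comparisons of the double mutant with a single mutant. With labels exchanged only within a replicate number, only the real one of 100 gave 8 in control (highest other 1). In limma 831 genes had an unadjusted p under 0.05 in control, against 828 expected by chance in a calibrated test. The same fit gave 418 for hd2c against WT in control, so 828 may not be the chance level there and 831 decides nothing. AT3G01345 also counts among the 8, and no other of them kept its call in every fit without 1 array. Chance is therefore not excluded for the other genes called there. In heat the highest other grouping called 79 genes, with hd2c heat replicates 1 and 3 beside brm heat replicate 1. Exchanged only within a replicate number, 2 drawings of 100 disagreed there: 2 gave 33 or more in the first (highest other 125) and 1 in the second (highest other 27). The source of the counts of 79 and 125 was not tested, so chance is not firmly excluded for the count in heat. Without taking out additive effects 5 and 19 of 100 groupings gave as many genes (highest other 151 and 659).

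Probe sets without a gene name, which the report leaves out, also responded to heat. Of 20904, 2128 were called in WT, 3106 in hd2c, 2470 in brm and 3295 in the double mutant. The largest changes in WT were probe sets 13473284 (8.18) and 13514081 (6.75), which rose, and 13392927 (−3.36) and 13488230 (−3.25), which fell.

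AT3G01345 was low in every mutant group, with 8.32 to 9.42 on WT arrays and 3.08 to 5.34 on mutant arrays. A segment deleted or silenced across neighbouring genes is argued against, since the median fold change of 7 expressed neighbours over the 6 comparisons was 0.0513 (range −0.45 to 0.56). Expressed here means above the dimmest 30% of genes in WT. AT3G01326 and AT3G01329 had WT means of only 2.11 and 2.25, near the arrays' lower quartile (1.92 to 2.13), where a fall could hardly show. A loss confined to AT3G01345 or to unmeasured neighbours was not tested. Under cyclic loess of the deposited values the smallest of the 6 falls was still −3.87. With array medians between 3.42 and 3.65, a new scaling could hardly have removed falls of this size. The outcome was thus fixed in advance and adds no evidence. Cyclic loess cannot undo the authors' normalization, which stays untested. The probe set of AT3G01345 was the only 1 of 38408 with this pattern. A difference between the WT plants and all mutant lines that neither mutation made stays open, because the design confounds it with genotype. A role of both BRM and HD2C in the expression of AT3G01345 may explain it, as may such a line difference, and the 2 cannot be told apart for this gene.

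Several heat-shock genes had higher levels in the heated mutants than in heated WT plants. In the difference of heat responses, limma called 0 of 11 small heat shock proteins in hd2c (8 at an unadjusted p under 0.05), 0 in brm (5) and 1 in the double mutant, and the list lost its calls with an estimated correlation (adjusted p = 0.124, 0.261 and 0.198). Scaling differences left between the arrays are argued against as the whole cause. Under cyclic loess of the deposited values the median of 11 small heat shock proteins in the double mutant against WT in heat was still 1.32. The authors' normalization was not undone by this and stays untested. A single larger amplitude for every heat-responsive gene (ratio to WT 1.23 ± 0.07 in the double mutant, 1.30 ± 0.11 in hd2c and 1.08 ± 0.06 in brm, jackknife SE) stays open. These ratios come from covariances with the responses of the other 2 mutants, whereas the mean scores in the report give 1.27, 1.28 and 1.10. Both measures rise where the mutants share a response that WT lacks, also without a larger amplitude for every gene. After scaling the WT response by 1.23, 58.8% of the 243 genes remained called. The 100 lost calls do not show that amplitude explains those genes, since their median difference went only from 1.05 to 0.91 while the median SE rose from 0.239 to 0.267. Of these 100, 18 moved towards 0 by more than 1 SE. The median of small heat shock proteins went from 1.11 to −0.14, while that of the cold response list went from 1.05 to 0.93. A stronger effective heat exposure of the mutant plants stays open, because genotype and exposure are confounded in this design. The exact permutation p of the amplitude score, 0.1, is the smallest possible and decides nothing. Equally open is an effect of the mutations on chaperone genes.

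Expression differences in the brm background could come from sequence variants linked to BRM. In control, called genes were no more frequent within 100 annotated genes on each side of the locus (2 of 73, 2.74%, against 4.27% elsewhere; odds ratio 0.632, 95% interval 0.0749 to 2.38), and the intervals in heat (4 of 73, 5.48% against 5.10%, odds ratio up to 2.90) and for the double mutant against hd2c in control (1 of 73, up to 2.36) also stayed under 3. These values show no excess of called genes near BRM. They do not decide on the main source, since 73 measured genes could not hold most of the 705 called in control at any odds ratio. Variants elsewhere in the brm line were not tested. Around HD2C linkage stays open: for the double mutant against brm in heat 7.55% of genes were called against 4.78% elsewhere (odds ratio 1.63, 95% interval 0.681 to 3.35). For hd2c against WT in heat 1 of 106 genes was called (odds ratio 1.59, 95% interval 0.0395 to 9.25), too few to decide. AT5G03750, 2 annotated genes from HD2C and chosen after its value was seen, was higher by 1.54 in hd2c against WT in heat (1.42 to 1.61 without 1 array, called in each fit). It was not called in hd2c against WT in control (0.18). In heat it was not called in the double mutant against WT (0.09) or against brm (0.28), although the double mutant carries the same hd2c-3 allele. It departed from additivity in heat by −1.25. Scaling differences left between the arrays are argued against. The correlation of the brm effect with and without HD2C in control was 0.560 under cyclic loess of the deposited values. The authors' normalization was not undone by this and stays untested. An effect of BRM loss on these genes remains a hypothesis.

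For the 14 comparisons of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05. Heat responses had 2198, 3316, 2613 and 3553 genes in WT, hd2c, brm and the double mutant (highest other 0, 0, 0 and 1). In control, hd2c against WT had 1 gene (highest other 1, so that 2 of the 10 splits gave as many), brm 705 (0), and the double mutant 517 against WT (0), 543 against hd2c (1) and 7 against brm (1). In heat, hd2c had 99 (1), brm 844 (0), and the double mutant 1545 against WT (7), 833 against hd2c (39) and 794 against brm (79), each with the highest other split in parentheses. In the other 13 comparisons 1 of the 10 splits, the real one, gave as many genes. In the 3 comparisons where replicate numbers pair the arrays, the 3 other splits that part as many pairs gave at most 0 genes (brm against WT in heat), 1 (double mutant against hd2c in control) and 0 (double mutant against brm in control).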

How the results depend on the processing

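The tests of all probe sets together and of a replicate block within condition were chosen only after results were seen. No named gene changed direction under cyclic loess, a replicate block or without 1 array, and no called list under the block or without the dimmest genes. The majority of calls turned under the 2 other scalings in 5 comparisons. With equal array medians the share of higher genes went from 52.2% to 41.2% (brm against WT in control), 46.1% to 54.2% (heat in brm), 42.9% to 60% (double mutant against brm in control) and 37.5% to 100% (additivity in control), and under cyclic loess from 43.7% to 51.6% (heat in the double mutant). Other settings turned it too where higher and lower counts were close or few. In control, array weights gave 469 higher and 433 lower for the double mutant against WT (254 and 263 in the report) and 430 and 414 against hd2c (266 and 277).

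The heat responses stayed within 1.5 times their count under every alternative, at 1549 to 1808 genes without 1 array in WT, 2563 to 3221 in hd2c, 2001 to 2158 in brm and 2854 to 3536 in the double mutant. Other counts without 1 array ranged more widely. Against WT in control they were 1 to 2 (hd2c), 458 to 554 (brm) and 308 to 379 (double), and in heat 3 to 357, 586 to 672 and 1093 to 1747. The double mutant gave 339 to 476 against hd2c and 1 to 41 against brm in control, and 592 to 801 and 384 to 1164 in heat. Differences in heat response gave 0 to 71 (hd2c), 11 to 33 (brm) and 138 to 311 (double), and departures from additivity 1 to 37 in control and 6 to 71 in heat. Fewer arrays lower the power by construction, while the cause of the rises was not tested.

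Array weights gave 3, 1322 and 902 genes for hd2c, brm and the double mutant against WT in control, 1290 for brm against WT in heat, 844 and 14 for the double mutant against hd2c and brm in control, 504 against hd2c in heat, 7 and 180 for the differences of hd2c and brm, and 17 for additivity in control. Fits of only the arrays compared, with fewer degrees of freedom by construction, gave 3, 531 and 694 against WT in heat, 215 and 165 for the double mutant against hd2c and brm in heat, 1 for the difference of hd2c, and 1 and 3 for additivity in control and heat. An intensity trend with robust moderation gave 151 for hd2c against WT in heat, 2 and 71 for the differences of hd2c and brm, and 57 for additivity in heat. Without moderation these were 64 for hd2c against WT in heat, 0 for the double mutant against brm in control, and 2 and 13 for additivity. Cyclic loess gave 3 and 59 for the differences of hd2c and brm, a common array median 3 and 63, with 2 for additivity in control, and leaving out the dimmest 30% gave 53 for brm. Testing all probe sets together gave 20 for the difference of brm, and 2 and 16 for additivity. The cause of these moves was not tested, and fewer degrees of freedom need not be the only one in fits of only the arrays compared. With the same loss of them, brm against WT in control gave at least 604 genes (705 in the report). The double mutant against hd2c in control gave at least 452 (543 in the report). The median SD within a group was 0.171 in hd2c heat and 0.186 in double mutant heat, against 0.109 in WT control.

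With a replicate block, the differences gave 2 (hd2c) and 51 (brm) genes and additivity in control 5, and with the block within condition the differences gave 16 and 84 and additivity in heat 56, and the cause was not tested. Elsewhere the block moved no count by over 1.5 times. Of 627 gene results 615 kept their call and 12 lost it, and of 101 list calls 99 were kept. The cold response list lost its call under the block in the WT heat response and in brm against WT in heat (adjusted p = 0.0581 and 0.0550, and over all alternatives 0.0581 to 0.257 and 0.0550 to 0.239). Same-numbered arrays correlated with r from −0.18 to 0.42 (median 0.069). In 3 of the 14 comparisons every array correlated best with its own number. Between genotypes in control, 4 to 6 of the 6 arrays did so in each comparison, so the pattern is wider than these 3.

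Of 627 gene results 418 kept their call in every fit without 1 array, and 615 kept it under cyclic loess. Of 101 list calls 21 held with an estimated correlation and 87 without the dimmest genes. No scaling moved the median of all genes by over 0.1.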

Other observations

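The list of mitotic genes and its tests were chosen only after AUR1, TOPII, BUBR1 and BUB3.1 had been seen, and other values here come from planned tests. The cell division genes AUR2, BUBR1, BUB3.1 and TOPII were called lower with heat in all 4 genotypes. In WT, AUR1 fell by 0.98, AUR2 fell by 1.21, BUBR1 fell by 1.00, BUB3.1 fell by 0.69 and TOPII fell by 0.45. In hd2c BUBR1 fell by 1.50 and TOPII fell by 0.96, and in brm they fell by 1.16 and 0.49. In the double mutant BUBR1 and BUB3.1 of the spindle checkpoint fell by 2.05 and 1.73, the Aurora kinase AUR1 fell by 1.69 and the topoisomerase TOPII fell by 1.49 (n = 3 per group). Of 3 further mitotic genes with a named probe set, AUR2 fell by 1.75, AUR3 fell by 0.53 and BUB3.2 fell by 0.51, and all 3 were called (camera adjusted p = 0.0149, and 0.0805 with an estimated correlation). As a list these 3 were not called in the heat response of WT (adjusted p = 0.194), hd2c (0.102) or brm (0.271), where AUR3 and BUB3.2 were not called either. Their difference in heat response between the double mutant and WT had a median of −0.54 with 0 of 3 called by limma (adjusted p = 0.0252, and 0.0934 with an estimated correlation). No explanation was tested.

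Some further genes from the naming rule are not given in the report. In the brm control plants the chitinase CHI rose by 1.78 ± 0.28, the glutamate receptor-like GLR2.8 by 1.67 ± 0.30 and the beta-glucosidase BGLU45 by 1.35 ± 0.14, while UGT85A2 fell by 1.45 ± 0.18. In the WT heat response the cation exchanger CHX16 fell by 2.25 ± 0.22, the sucrose phosphate synthase ATSPS4F fell by 2.08 ± 0.21 and the expansin EXPA16 fell by 1.67 ± 0.21, whereas the expansin-like EXLA1 rose by 1.61 ± 0.29. In the double mutant the clock gene GI fell by 0.77 ± 0.14 against hd2c in control.

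Lists meant to show other tissue or handling had few named members. Root markers had 3 of 12 measured, floral organ genes 0 of 11, leaf senescence 1 (SAG101, 0.85 ± 0.19 in the double mutant against hd2c in heat) and touch response 1 (STZ, 1.46 ± 0.34 in the double mutant's heat response). The root list was called in none of the 19 comparisons (camera adjusted p from 0.373 to 0.992), with at most 1 of its 3 genes called in any. The floral list could not be tested, and the others rest on 1 gene each, so a difference in tissue composition stays largely untested. The median SD of a gene within a group was 0.109 in WT control, 0.140 in WT heat, 0.171 in hd2c heat and 0.186 in double mutant heat, the largest of the 8 groups.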
